A study of Mus musculus with 4 samples.

How the data were processed

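The series holds 4 samples from cultured mouse oligodendrocyte progenitor cells: an input library without antibody and 3 RNA polymerase II ChIP-seq libraries, from OPCs, from oligodendrocytes matured with (R)-JQ1 and from oligodendrocytes matured with (S)-JQ1. Per the labels' protocols, the compound was added after the cells had attached, followed by thyroid hormone (T3), which drives maturation. Groups were taken from the sample titles. The input library's title names OPCs while its treatment entry describes cells differentiated with (R)-JQ1, and it was not used here. No label names replicates, doses or maturation times.

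The submitters' processing notes name Bowtie 0.12.9, MACS 1.4, Cufflinks and the mouse genome build mm9, with no role for each. Whether the input served as control in peak calling, and the read depth of each library, are not given in the sources used here. The authors deposited 1 peak list per library, with a position, a peak name and a score for each peak. The score in the deposited lists has the scale of MACS 1.4, 10 times the negative log10 of the peak's p-value: the lowest score was 50.0, which stands for a p-value of 1e-05, and the highest was 3233, the smallest p-value that double precision can hold. Exactly 3100 was recorded for 449 OPC, 453 (R)-JQ1 and 61 (S)-JQ1 peaks, and 46, 49 and 9 peaks had higher scores. A repeated value of this kind can stand for a p-value too small to compute, so the order among peaks at or above 3100 is not informative. The score depends on depth, so it was used only to rank or filter peaks within a list, and medians across lists are given as description. Median scores were 230.9 in OPCs, 301.4 with (R)-JQ1 and 199.0 with (S)-JQ1, and median widths were 1472, 1545 and 1398 bp.

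Positions were treated as counted from 0 at the start, as in the BED format, and are printed counted from 1. The build was checked against chromosome lengths: 19 chromosome 1 peaks ended beyond the 195471971 bp of chromosome 1 in GRCm38, and all ended within the 197195432 bp of mm9. The gene table at hand gives positions in GRCm38, and positions were not converted between builds. For that reason no peak was assigned to a gene, exon or promoter, sites are named by position, and the 16 gene lists fixed for the study (progenitor, myelin and other marker genes) were not analysed here.

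Peak lists were intersected with bedtools 2.31.1, and an overlap of at least 1 bp counted as shared. Merged regions are sets of peaks linked by such overlaps across the 3 lists. Shares carry exact (Clopper-Pearson) 95% intervals, computed with scipy 1.17.1 in Python 3.11.15, and neighbouring peaks are not independent, so they are too narrow as statements on the cells. A chance level for each overlap came from 100 random circular shifts of the second list along each chromosome. Peaks were split into 5 equal groups by score (quintiles) to compare like with like. A score-matched share weights peaks that have a counterpart to the score distribution of those that do not, over 20 score bins, with 1000 bootstrap resamples of peaks. Widths were compared at regions with 1 peak in each library. With 1 library per group no test between conditions can be made. Where intervals of shares, or a bootstrap difference, are set side by side, they compare these peak lists and not the conditions. On lists simulated from the 18585 (R)-JQ1 peaks, overlap shares were recovered to within 0.205 percentage points and a set score-matched deficit to within 0.731 percentage points. For the deficit the other lists were drawn by score rank, so error of the score as a measure of strength was not simulated.

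Groups, comparisons, the alternatives and the naming rule were fixed before the data were examined. The rule named, per library, the 5 peaks with the highest score and the 5 widest, per ordered pair of libraries the 5 highest-scoring peaks without a counterpart, and the 5 merged regions of largest summed covered length. Of the first 2 kinds, only the peak or peaks with the top score are given by position, and the rest are summarised. The alternatives fixed then were an overlap of 50% of the shorter or of each peak, the upper 50% of each list by score, the 12101 highest-scoring peaks of every list, autosomes and X only, and merging of peaks within 500 bp. The score quintiles, the score matching, the random shifts, the runs of specific peaks, the 1 Mb windows and the mapped regions were added after the lists had been opened, and runs, windows and maps were chosen after their values were seen. The limit of 5 kb for wide peaks, its alternatives of 3 and 10 kb, merging within 2 kb, and the removal of 2 crowded places on chromosomes 2 and 9 were chosen after the data were seen.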

Results

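RNA polymerase II occupancy was profiled by ChIP-seq in mouse oligodendrocyte progenitor cells (OPCs) and in oligodendrocytes matured from them in the presence of either enantiomer of JQ1. Chromatin was precipitated with 8WG16, an antibody against the repeated C-terminal tail of the largest polymerase subunit. The (S) enantiomer of JQ1 binds the bromodomains of the BET proteins, a family of chromatin readers that helps recruit the transcription elongation machinery, and the (R) enantiomer is its inactive mirror image. There was 1 ChIP library per group, so every comparison below is between 3 single libraries with no replicate check, and the intervals given cover only the counting of peaks. The OPC library had 16725 peaks covering 30.5 Mb, the oligodendrocyte library with (R)-JQ1 had 18585 peaks covering 33.5 Mb, and the oligodendrocyte library with (S)-JQ1 had 12101 peaks covering 19.1 Mb. The mean peak width was 1823 bp, 1801 bp and 1575 bp in that order. The read depth of the libraries is unknown from these peak lists, and both the number and the score of peaks rise with depth.

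The first comparison, OPCs against oligodendrocytes matured with the inactive enantiomer, addresses how polymerase sites differ between the progenitor and the maturing cell. Most sites were common to both: 81.0% of OPC peaks (exact 95% interval 80.4 to 81.6) overlapped a peak of the oligodendrocyte list, and 72.6% of oligodendrocyte peaks (71.95 to 73.24) overlapped an OPC peak. When the peaks of the other list were moved at random along each chromosome, the mean overlaps were 2.64% and 2.37%. There were 3181 OPC peaks with no oligodendrocyte counterpart and 5092 oligodendrocyte peaks with no OPC counterpart. These list-specific peaks were mostly weak, with a median score of 77.0 in OPCs and 79.6 in oligodendrocytes, beside 343.9 and 584.1 for the shared peaks of the same lists. In the highest score quintile of each list, 0.957% of OPC peaks and 0.377% of oligodendrocyte peaks had no counterpart.

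A small set of high-scoring sites separated the progenitor from the oligodendrocyte list. The OPC peak on chromosome 16 from 22237976 to 22245729 (all positions in mm9) was 7.75 kb wide, had a score of 3100 and lay 18.9 kb from the nearest oligodendrocyte peak. OPC peaks of 8.55 kb on chromosome 15 (36709193 to 36717740), 6.40 kb on chromosome 19 (21355902 to 21362303), 2.81 kb on chromosome 17 (46682466 to 46685271) and 17.7 kb on chromosome 7 (135115629 to 135133368) followed by score. Each of these 4 lay between 1.62 and 6.13 kb from an oligodendrocyte peak. In the other direction, the oligodendrocyte peak with the highest score and no OPC counterpart was on chromosome 1 from 174220475 to 174228918, 8.44 kb wide with a score of 3071 and 10.6 kb from the nearest OPC peak. Next came peaks on chromosome 14 (70948791 to 70955908, score 1943), chromosome X (50404988 to 50408276, score 1881) and chromosome 11 (69177736 to 69182933, score 1791, and 102796430 to 102802412, score 1625), which lay 2.99, 1.43, 25.4 and 5.04 kb from an OPC peak. Of these 5 oligodendrocyte sites, the first 4 also carried an (S)-JQ1 peak and the last did not.

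OPC-specific peaks lay in groups and near oligodendrocyte peaks more often than oligodendrocyte-specific peaks lay in groups and near OPC peaks. Of the OPC peaks without an oligodendrocyte counterpart, 52.8% (51.1 to 54.6) lay within 10 kb of an oligodendrocyte peak, against 28.1% (26.9 to 29.4) of oligodendrocyte-specific peaks within 10 kb of an OPC peak. Runs of 3 or more specific peaks no more than 25 kb apart held 22.4% of the OPC-specific peaks (21.01 to 23.94) and 8.86% of the oligodendrocyte-specific ones (8.09 to 9.67). No chance level was computed for these shares. OPC peaks also lay close together more often over the whole list: merging within 2 kb left 15009 of 16725, beside 17307 of 18585 with (R)-JQ1. The longest OPC run had 9 specific peaks over 58.4 kb of chromosome 6 (49153001 to 49211373). Within that span, OPC peaks covered 20.1 kb, (R)-JQ1 peaks 4.51 kb and (S)-JQ1 peaks 2.70 kb. A run of 8 OPC-specific peaks on chromosome 11 (80204923 to 80225121) covered 14.3 kb, and neither oligodendrocyte list had a peak there. Among runs specific to oligodendrocytes with (R)-JQ1 against OPCs, 1 on chromosome 19 (6445138 to 6499353) held 6 peaks covering 8.92 kb and 1 on chromosome 17 (25792067 to 25817835) held 5 peaks covering 13.2 kb, both with no peak in the OPC list or the (S)-JQ1 list. A run of 6 on chromosome 15 (78927687 to 79007235) covered 15.5 kb. Its span held 6 (S)-JQ1 peaks covering 23.7 kb, beside 9 (R)-JQ1 peaks covering 37.0 kb and 4 OPC peaks covering 8.20 kb. How many of these (S)-JQ1 peaks lay at the specific peaks was not counted.

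**Figure D1:**
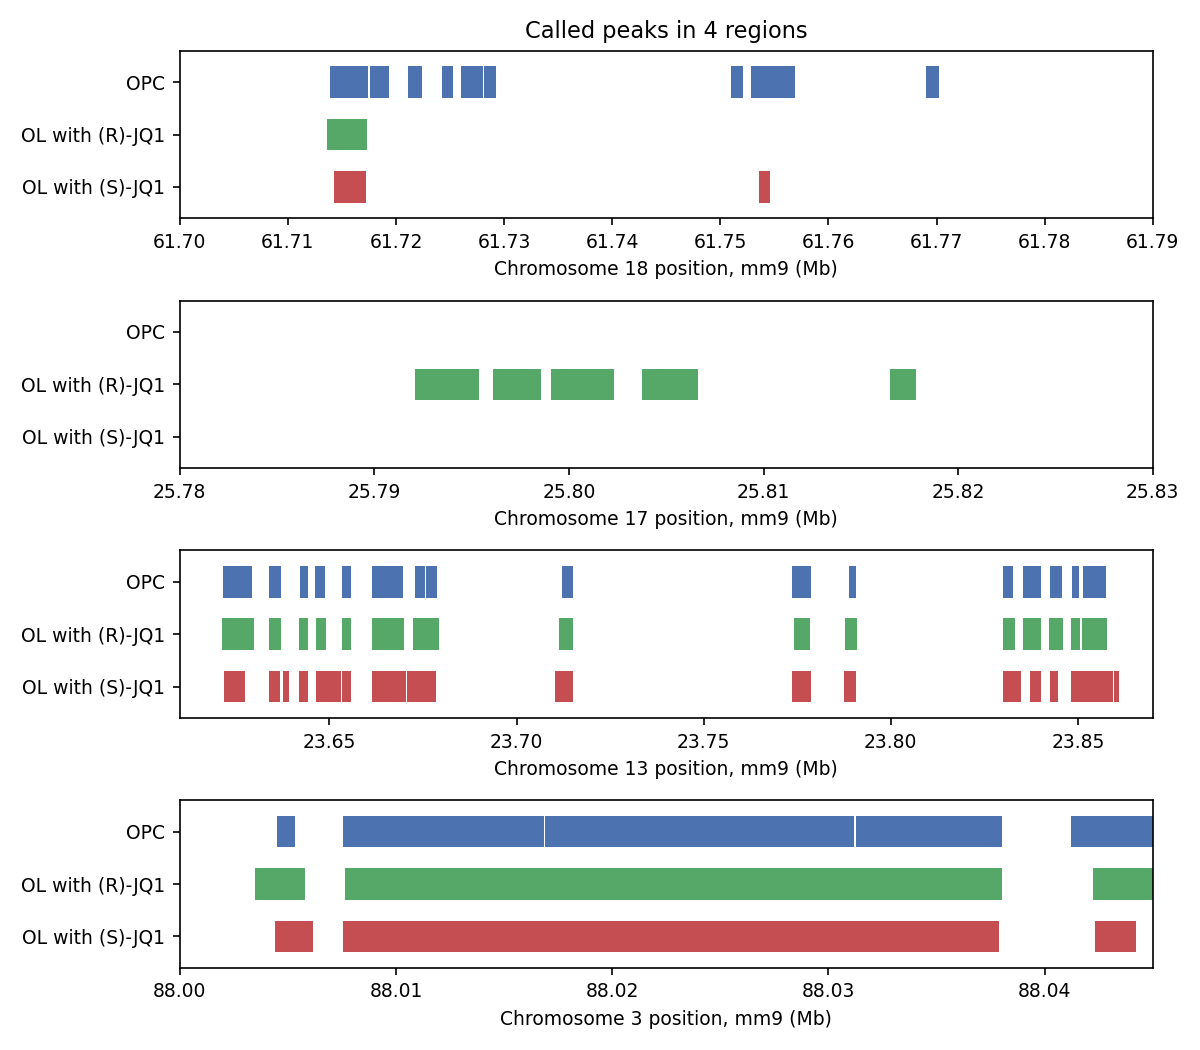
Peaks called in 4 regions of the mouse genome; the horizontal axis is the mm9 position in Mb, each row is 1 library, and each filled bar is a called peak drawn to scale. On chromosome 18 OPCs had 9 peaks and the oligodendrocyte libraries 1 and 2, on chromosome 17 only the (R)-JQ1 library had peaks (5), on chromosome 13 the (S)-JQ1 peaks covered 73.9 kb beside 66.9 kb with (R)-JQ1 and 60.3 kb in OPCs, and on chromosome 3 the 3 lists covered nearly the same block.

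The second comparison sets the active against the inactive enantiomer in oligodendrocytes matured with each. The labels give neither dose nor time, so whether both cultures matured equally is not known. The (S)-JQ1 list was close to a subset of the (R)-JQ1 list. Of the (S)-JQ1 peaks, 96.4% (96.1 to 96.8) overlapped an (R)-JQ1 peak, while 61.3% of (R)-JQ1 peaks (60.6 to 62.0) overlapped an (S)-JQ1 peak. The mean overlaps after random movement were 2.49% and 1.63%. The 7186 (R)-JQ1 peaks without an (S)-JQ1 peak had a median score of 84.3 and a median width of 1105 bp, beside 747.2 and 1852 bp for those with one. Among the weakest quintile of (R)-JQ1 peaks 10.04% had an (S)-JQ1 peak (9.09 to 11.05), among the strongest quintile 99.92% did (99.76 to 99.98), and in the upper 2 quintiles together 109 of 7434 peaks (1.47%, 1.21 to 1.77) had none. With both lists limited to their 12101 highest-scoring peaks, 85.4% of (R)-JQ1 peaks overlapped an (S)-JQ1 peak and 87.9% the reverse. At that equal number 82.7% of (R)-JQ1 peaks overlapped an OPC peak, so the order turned: over the whole lists (R)-JQ1 peaks had an OPC counterpart more often than an (S)-JQ1 one (72.6% and 61.3%), and over lists of equal number the reverse.

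The 5 highest-scoring (R)-JQ1 peaks with no (S)-JQ1 peak are given by position. The first was the peak on chromosome 11 from 102796430 to 102802412 (score 1625, 5.98 kb wide), which had no OPC peak either, although (S)-JQ1 and OPC peaks lay 4.95 and 5.04 kb away. A further peak on the same chromosome, from 102754195 to 102760412 (score 1219), lay 11.4 kb from the nearest (S)-JQ1 peak and 0.971 kb from an OPC peak. The peak on chromosome 1 from 194571222 to 194574002 (score 1408) overlapped an OPC peak, and its nearest (S)-JQ1 peak was 382 kb away. On chromosome 8 the peak from 125954704 to 125958135 (score 1070) overlapped an OPC peak and had an (S)-JQ1 peak at 0.43 kb. On chromosome 17 the peak from 25792067 to 25795384 (score 1051) was 75.1 kb from any (S)-JQ1 peak and 75.2 kb from any OPC peak. Only 431 (S)-JQ1 peaks had no (R)-JQ1 counterpart, with a median score of 59.3. The 3 strongest of these were on chromosome 13 (21912482 to 21914003, score 684, and 23637553 to 23639264, score 509) and chromosome 3 (96084337 to 96086865, score 338). They lay 8.75, 0.628 and 0.179 kb from the nearest (R)-JQ1 peak, in that order. The next were on chromosome 2 (98502200 to 98503367, score 226) and at the start of chromosome 9 (3001908 to 3003227, score 181). Both lie in the crowded places whose removal was an alternative, where every list had peaks, so they are not read as sites particular to (S)-JQ1.

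**Figure D2:**
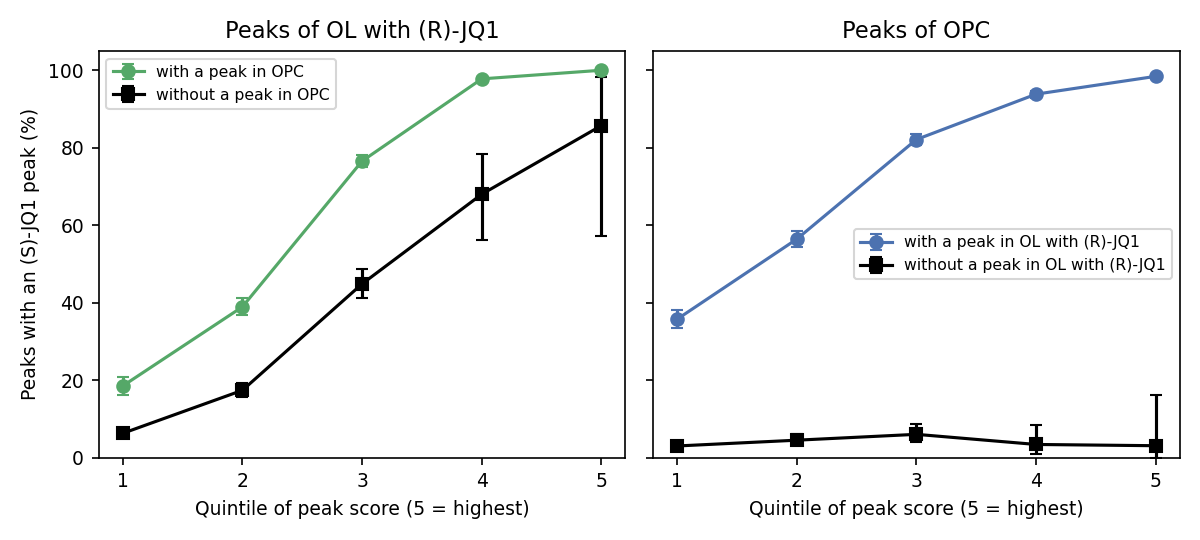
Share of peaks (%, vertical axis) that overlapped an (S)-JQ1 peak, by quintile of the peak's own score (horizontal axis, 5 = highest), for (R)-JQ1 peaks with and without an OPC peak (left) and OPC peaks with and without an (R)-JQ1 peak (right); bars are exact 95% intervals. For (R)-JQ1 peaks without an OPC peak the share was 6.31% in the lowest quintile and 85.7% in the highest, which holds 14 peaks, whereas for OPC peaks without an (R)-JQ1 peak it lay between 3.055% and 6.06% in every quintile.

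Where the progenitor and the (R)-JQ1 oligodendrocyte lists differed, the (S)-JQ1 list held more of the oligodendrocyte-specific peaks than of the OPC-specific ones. Of the 5092 oligodendrocyte peaks absent from OPCs, 16.4% (15.4 to 17.5) had an (S)-JQ1 peak, and of the 3181 OPC peaks absent from (R)-JQ1 oligodendrocytes, 3.96% (3.31 to 4.70) did. The latter share had little room, because only 431 (S)-JQ1 peaks lay outside the (R)-JQ1 list. For peaks that both lists held, the shares were 78.3% (77.6 to 79.0) of (R)-JQ1 peaks and 78.4% (77.7 to 79.1) of OPC peaks. Among oligodendrocyte peaks absent from OPCs, the share with an (S)-JQ1 peak was 44.9% (41.1 to 48.7) in the middle score quintile, beside 76.54% (74.985 to 78.04) of those with an OPC peak. Among the 14 in the highest quintile it was 85.7% (57.2 to 98.2), beside 99.97% (99.85 to 99.999) of 3703 with an OPC peak, and among the 75 in the quintile below it was 68.0% (56.2 to 78.3). With equal numbers of peaks per list, the share for oligodendrocyte peaks absent from OPCs was 52.2% and that for OPC peaks absent from (R)-JQ1 oligodendrocytes was 18.9%; with an overlap of 50% of each peak required, the latter was 13.2%.

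Merging overlapping peaks of the 3 lists gave 21805 regions, of which 10450 (47.9%, 47.3 to 48.6) had a peak in every library. Regions present in both oligodendrocyte libraries and not in OPCs numbered 812, beside 125 present in OPCs and (S)-JQ1 oligodendrocytes and not with (R)-JQ1. A further 4255 regions were held by (R)-JQ1 oligodendrocytes alone, 3055 by OPCs alone and 295 by (S)-JQ1 oligodendrocytes alone. Regions common to OPCs and (R)-JQ1 oligodendrocytes with no (S)-JQ1 peak numbered 2813. With equal numbers of peaks per list, the regions of both oligodendrocyte libraries alone and of OPCs and (S)-JQ1 alone numbered 1083 and 388. The order of the regions held by a single library depended on list length, with 1661 for OPCs, 1053 for (S)-JQ1 and 1002 for (R)-JQ1 at equal numbers.

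**Figure D3:**
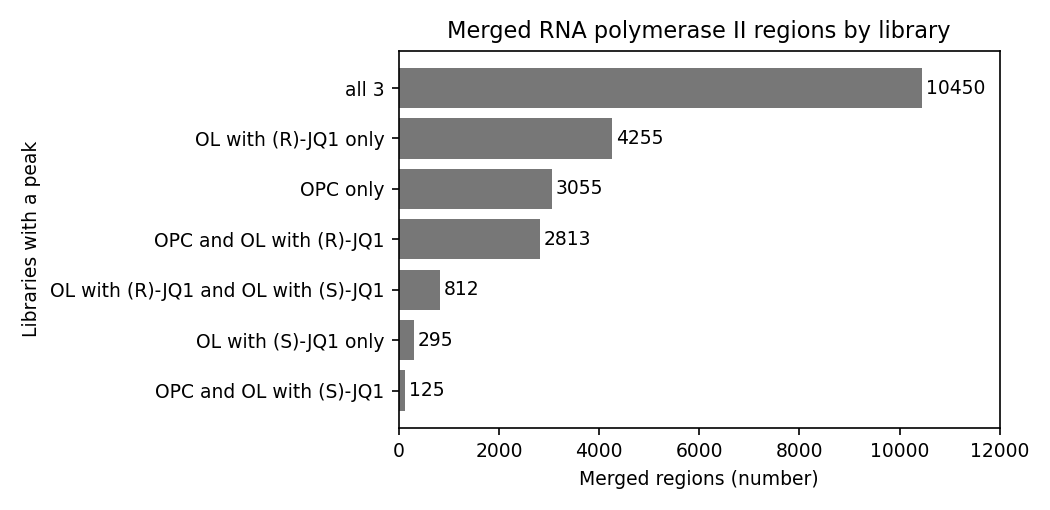
Number of merged regions (horizontal axis) for each combination of libraries with a peak (vertical axis). The bar for all 3 libraries holds 10450 regions, and the smallest, OPCs with (S)-JQ1 oligodendrocytes only, holds 125.

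The direct comparison of OPCs with oligodendrocytes matured under the active enantiomer gave the lowest overlap by length over the whole lists. OPC and (S)-JQ1 peaks shared 16.6 Mb, or 50.5% of the length either covered, beside 53.1% for the 2 oligodendrocyte lists and 54.6% for OPCs and (R)-JQ1 oligodendrocytes. These shares are capped by list length, since (S)-JQ1 peaks covered 19.1 Mb beside 30.5 Mb in OPCs and 33.5 Mb with (R)-JQ1. Their order alone does not rank how alike the cells were. Of the (S)-JQ1 peaks 90.2% (89.7 to 90.7) overlapped an OPC peak, and 64.2% of OPC peaks (63.5 to 65.0) overlapped an (S)-JQ1 peak. OPC peaks at a score of 3100 without an (S)-JQ1 peak included 1 on chromosome 1 (88238690 to 88247275), 1 on chromosome 11 (118931543 to 118944935), 1 on chromosome 12 (82051193 to 82060703) and 1 on chromosome 14 (70473861 to 70482019), all of which overlapped an (R)-JQ1 peak, and the chromosome 16 peak named above, which did not. The (S)-JQ1 peaks with the highest scores and no OPC counterpart were on chromosome 13 (21920450 to 21922989, score 844, and 21912482 to 21914003, score 684) and chromosome 16 (42906796 to 42908372, score 644), followed by peaks on chromosome 11 (100441010 to 100448312, score 596) and chromosome 13 (23637553 to 23639264, score 509). The nearest OPC peaks lay 0.18, 9.17, 30.0, 3.36 and 0.628 kb from these, in that order.

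Peaks called with the active enantiomer were also narrower at the same sites. At the 9888 regions with exactly 1 peak in each library, the median width was 1642 bp in OPCs, 1854 bp with (R)-JQ1 and 1427 bp with (S)-JQ1. Scores ranked the libraries alike: over the 10450 regions of all 3, median top scores were 510.7, 813.2 and 234.2 in that order. With depth unknown, the narrower calls cannot be told apart from a lower signal in the (S)-JQ1 library. The median log2 ratio of widths was 0.13 for (R)-JQ1 over OPCs (quartiles -0.06 and 0.34), -0.33 for (S)-JQ1 over (R)-JQ1 (-0.55 and -0.15) and -0.18 for (S)-JQ1 over OPCs (-0.42 and 0.01), and 91.2% of the regions were narrower with (S)-JQ1 than with (R)-JQ1. Peaks wider than 5 kb numbered 476 in OPCs (2.85% of peaks, 2.599 to 3.109), 358 with (R)-JQ1 (1.93%, 1.73 to 2.13) and 112 with (S)-JQ1 (0.926%, 0.763 to 1.11). At a limit of 3 kb OPCs had the lower count in a shorter list, 1553 beside 1582 with (R)-JQ1, but the higher share of peaks, 9.29% beside 8.51%, and at 10 kb the counts were 72 and 34.

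**Figure D4:**
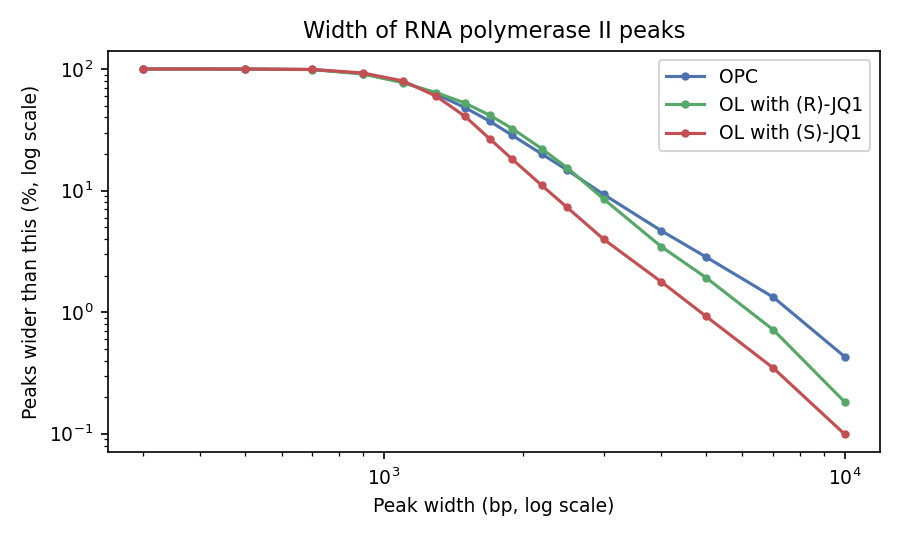
Share of peaks wider than a given width (vertical axis, %, log scale) against that width (horizontal axis, bp, log scale) for each library. The (S)-JQ1 line lies lowest from 1300 bp upward, and the OPC and (R)-JQ1 lines cross between 1100 and 1300 bp and again between 2500 and 3000 bp.

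The 5 merged regions of largest summed covered length had peaks in all 3 libraries, and a sum over the 3 lists favours regions they share. The 5 peaks with the highest score and the 5 widest peaks of each list all overlapped a peak of both other lists. The top score of each list was that of OPC peaks on chromosome 12 (45309189 to 45311830) and chromosome 7 (148040563 to 148043982), an (R)-JQ1 peak on chromosome 12 (39504828 to 39511911) and an (S)-JQ1 peak on chromosome 5 (43623294 to 43626823). The order among scores this high is not reliable, since many peaks share a recorded value of 3100. The largest merged region by summed covered length, on chromosome 3 from 88007546 to 88038047, was covered over 30.4 kb in OPCs, 30.4 kb with (R)-JQ1 and 30.4 kb with (S)-JQ1. The region on chromosome 13 from 83858610 to 83883054 was covered over 24.4, 20.9 and 22.2 kb, and a second region of chromosome 3 from 34546149 to 34566610 over 19.997, 20.23 and 19.94 kb. On chromosome 7 the region from 86640684 to 86662079 was covered over 21.4, 17.0 and 17.8 kb. The region on chromosome 6 from 52107765 to 52130092 was covered over 13.6 kb in OPCs, 22.1 kb with (R)-JQ1 and 18.9 kb with (S)-JQ1, where it was called as 9 separate peaks. OPC peaks wider than 5 kb were matched less completely than these: (R)-JQ1 peaks covered 55.8% of their summed length and (S)-JQ1 peaks 42.3%, beside 76.6% and 56.2% for narrower OPC peaks. For (R)-JQ1 peaks wider than 5 kb, (S)-JQ1 peaks covered 66.7% of the length, beside 53.4% for narrower ones.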

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

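No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The gene-based alternatives were not run, since gene positions in mm9 were not used here. Limits of 3, 5 and 10 kb on width, merging within 2 kb and the removal of crowded places were chosen after the data were seen. An overlap of 50% of the shorter peak, the restriction to autosomes and X, and the removal of crowded places each left all 17 shares and region counts within the interval or within 1.5 times the value as deposited. The width ratios kept their direction with peaks within 500 bp merged. With equal numbers of peaks several orders turned. (R)-JQ1 peaks then overlapped (S)-JQ1 peaks more often than OPC peaks, and more often than OPC peaks overlapped (S)-JQ1 peaks. Regions of (R)-JQ1 alone became fewer than those of OPCs alone, of (S)-JQ1 alone and of both oligodendrocyte libraries (1083), and regions of OPCs and (R)-JQ1 became fewer than those of both oligodendrocyte libraries and of (S)-JQ1 alone. At a width limit of 3 kb OPCs had the lower count of wide peaks and still the higher share, 9.29% beside 8.51% with (R)-JQ1. Requiring 50% of each peak gave 74.3% of OPC peaks overlapped with (R)-JQ1 and 58.7% with (S)-JQ1, 66.9% of (R)-JQ1 peaks overlapped in OPCs and 56.6% with (S)-JQ1, and 81.1% of (S)-JQ1 peaks overlapped in OPCs and 87.0% with (R)-JQ1. The shares with an (S)-JQ1 peak were then 20.4% of (R)-JQ1 peaks without and 74.5% with an OPC peak, and 13.2% of OPC peaks without and 74.4% with an (R)-JQ1 peak; 920 regions were held by (S)-JQ1 alone and 413 by OPCs and (S)-JQ1. In the upper 50% of each list, the same overlaps were 88.2%, 66.5%, 79.1%, 63.6%, 92.4% and 98.8%, and the same shares with an (S)-JQ1 peak were 20.9%, 74.9%, 3.24% and 74.97%. Regions then numbered 956 for OPCs alone, 1533 for (R)-JQ1 alone, 41 for (S)-JQ1 alone, 1817 for OPCs and (R)-JQ1, 31 for OPCs and (S)-JQ1, 403 for both oligodendrocyte libraries and 5476 for all 3, which follows from the shorter lists. With 12101 peaks in every list, the overlaps in that order were 83.1%, 79.8%, 82.7%, 85.4%, 81.5% and 87.9%, and the shares with an (S)-JQ1 peak were 52.2%, 92.4%, 18.9% and 92.2%. Regions numbered 1661 for OPCs alone, 1002 for (R)-JQ1 alone, 1053 for (S)-JQ1 alone, 734 for OPCs and (R)-JQ1 and 388 for OPCs and (S)-JQ1; the rise for (S)-JQ1 alone follows from cutting weak peaks out of the longer lists. The median widths of these 12101 peaks were 1705 bp in OPCs and 1872 bp with (R)-JQ1. Merging peaks within 500 bp gave median widths of 1488, 1564 and 1407 bp in OPCs, with (R)-JQ1 and with (S)-JQ1. Peaks wider than 3 kb numbered 1553, 1582 and 481 in that order, those wider than 10 kb 72, 34 and 12, and those wider than 5 kb after merging within 2 kb 860, 733 and 244. Beyond the shorter lists and the stricter overlap themselves, the cause of these shifts was not tested. The unknown depth of each library limits every comparison of peak numbers, widths and scores, and a missing peak means that none was called, not that polymerase was absent.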

Other observations

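The windows and the tests on the share of wide peaks and on chromosome 13 were chosen after the values were seen; the other tests were written down before their results were seen. Counted in 1 Mb windows, the genome differed widely in how much polymerase-covered sequence the lists held. Over 979 windows with at least 8 peaks in some list, the median ratio of covered length was 1.10 for (R)-JQ1 oligodendrocytes over OPCs, with quartiles of 0.914 and 1.34. The windows with the highest ratios were on chromosome 7 from 122 to 123 Mb (17.9 kb against 2.11 kb), chromosome 1 from 161 to 162 Mb (19.5 kb against 2.44 kb), chromosome 15 from 74 to 75 Mb (21.3 kb against 5.39 kb) and chromosome 18 from 82 to 83 Mb (21.3 kb against 6.03 kb). In these 4 windows (S)-JQ1 peaks covered 8.01, 4.70, 6.52 and 4.60 kb. The lowest ratio was on chromosome 16 from 8 to 9 Mb, where OPC peaks covered 43.3 kb, (R)-JQ1 peaks 14.0 kb and (S)-JQ1 peaks 10.4 kb.

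For (S)-JQ1 over (R)-JQ1 the median window ratio was 0.570 (quartiles 0.485 and 0.653). The lowest window, on chromosome 10 from 68 to 69 Mb, held 13 (R)-JQ1 peaks, 8 OPC peaks and 1 (S)-JQ1 peak. Its (R)-JQ1 peaks were weak, with a median score of 72.1. That score lies in the weakest quintile, in which 10.04% of all (R)-JQ1 peaks had an (S)-JQ1 peak. Chromosome Y, with 7 (R)-JQ1 peaks, was left out of the comparison of chromosomes. Among the autosomes and X, chromosome X had the lowest share of (R)-JQ1 peaks without an (S)-JQ1 peak, 23.9%, and chromosome 10 the highest, 42.9%. The same chromosomes were the extremes for (R)-JQ1 peaks without an OPC peak, at 17.1% and 31.8%. These extremes are therefore not particular to the active enantiomer, and the order of the chromosomes between them was not compared. At the start of chromosome 9, between 2999814 and 3038425, 5 OPC, 7 (R)-JQ1 and 8 (S)-JQ1 peaks crowded with scores of at most 234.9, and the ratio of its window from 3 to 4 Mb, 1.17, was the highest of all. It is one of the crowded places whose removal was an alternative, so its ratio is not read as a gain.

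Oligodendrocyte (R)-JQ1 peaks without an OPC peak had an (S)-JQ1 peak less often (16.4%) than those with one (78.3%). A lower (R)-JQ1 score together with a shorter (S)-JQ1 list is argued against as the whole cause. Matched on that score, (R)-JQ1 peaks with an OPC peak had an (S)-JQ1 peak in 32.4% (31.0 to 33.9). This share was above the interval of the observed share (15.4 to 17.5). Lower strength itself stays open, since a score measures strength with error and peaks also called in OPCs may be stronger at equal score. Whether any peak missing from one list is less often found in another stays open. OPC peaks without an (R)-JQ1 peak showed a larger score-matched deficit, 46.3 points against 16.0 points, a difference of -30.3 points (-32.6 to -28.2), but this decides nothing: only 431 (S)-JQ1 peaks lacked an (R)-JQ1 peak, 13.5% of the number of such OPC peaks, so the near nesting of the lists fixed the outcome. A selective sensitivity of sites without an OPC peak to the active enantiomer stays open and untested, since each condition has 1 library.

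The (S)-JQ1 list had 0.313 times as many peaks wider than 5 kb as the (R)-JQ1 list, while it had 0.651 times as many peaks. A shorter list with the same mix of widths is argued against, since the share of wide peaks was 0.926% with (S)-JQ1 and 1.93% with (R)-JQ1 (1.73 to 2.13). Breakage of broad peaks into pieces no more than 2 kb apart is argued against as well, since the ratio of wide counts was 0.333 after merging within 2 kb. Breakage with wider gaps was not tested. Lower signal over background or lower depth in the (S)-JQ1 library may narrow called peaks in the same way as a loss of polymerase from gene bodies, and peak lists alone hold no value that separates these.

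Against the general narrowing, 2 windows of chromosome 13, from 21 to 22 Mb and from 23 to 24 Mb, had more sequence covered with (S)-JQ1 than with (R)-JQ1: 51.0 against 48.5 kb and 80.3 against 77.5 kb, at ratios of 1.05 and 1.04. They were singled out after the ratios were seen, because the 2 strongest (S)-JQ1 peaks without an (R)-JQ1 counterpart lie in them. Of the 8 windows among 979 with a ratio above 1, those on chromosome 7 from 119 to 120 Mb (1.07), chromosome 11 from 88 to 89 Mb (1.07), chromosome 1 from 66 to 67 Mb (1.04) and chromosome 19 from 21 to 22 Mb (1.04) had similar ratios. Of 138 other windows with a median (R)-JQ1 score of at least 677.0, 0.725% had a ratio as high. The chromosome 19 window, with a median score of 1190, fell just short, at 1.0363 beside 1.03636. This decides nothing on high scores as the cause. The 2 windows were chosen for strong (S)-JQ1 peaks without an (R)-JQ1 counterpart, and such peaks raise the ratio. High scores, reads shared between near-identical sequences, more copies of these windows in the cells and a true gain of polymerase stay open, the last 3 untested.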
